A study of Arabidopsis thaliana with 8 samples.

How the data were processed

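Transcript levels of whole Arabidopsis thaliana seedlings were measured on 8 Affymetrix arrays, 1 for each RNA sample, with 2 biological replicates of each of 4 genotypes per the labels. The genotypes were wild type (Col-0), the gbf1 mutant, the gbf1 hy5 double mutant and the gbf1 hyh double mutant. Per the labels, the seedlings were 4 days old and had grown in constant white light of 20 µmol per square metre per second at 22 °C on medium with 1% sucrose, after 4 days at 4 °C. Per the labels, total RNA was isolated with an RNeasy kit and biotin-labelled amplified RNA was made with a 3' IVT Express kit. An ecotype is stated only for wild type per the labels. Differences of genetic background therefore cannot be told apart from effects of the mutations in any comparison below.

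Per the series design text, the arrays were analysed in GeneSpring with the RMA algorithm, and RMA is also named, without a version, per the submitters' processing notes. The deposited values were taken as log2 RMA signals. Their base is not stated in the sources used here and was taken from RMA's usual output. In all 22810 probe sets the median over the 8 arrays was 0 within 1e-06, so the deposited log2 values give each probe set's signal relative to its own median and hold no expression level. The largest range of 1 probe set over the arrays was 7.80. The raw array images were not used here, and no value was normalised again except in the alternatives below.

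The 64 AFFX control probe sets were left out of the tests, and 22746 probe sets were tested. The probe table tied 13513 of these to 1 gene, 503 to several genes and 8730 to none. For 11933 of the first group the gene had only a locus name. A reference gene table of assembly TAIR10.1 was used for names and for the order of neighbouring genes only, and 13436 of the probe sets with 1 gene were found in it. GBF1 and HY5 had no probe set of their own in the probe table used here, so HYH was the mutated gene that could be checked.

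Samples were grouped by the genotype in their labels. Of 6 comparisons, 5 are named in the series design text, and gbf1 hy5 against gbf1 hyh was added. The comparisons, tests, 21 gene lists, rule for named genes and alternatives were fixed before the data were examined, apart from those named as added. All 8 arrays were fitted in limma 3.58.1 (R 4.3.3) with lmFit, contrasts.fit and eBayes as 4 genotype means, without a replicate block, with 4 residual and 5.124 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the 22746 probe sets, and a probe set was called at an adjusted p under 0.05. Counts at 2-fold or more were also made. The number of arrays limits the precision.

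Gene lists were tested with limma's camera at a preset correlation of 0.01 among genes, adjusted over the lists of a comparison. The fixed lists held 344 members, of which 50 had a probe set of their own, and 9 lists with at least 3 measured members were tested. These covered light-harvesting proteins, chlorophyll biosynthesis, the Calvin cycle, the flavonoid pathway, auxin response, expansins with xyloglucan endotransglucosylases, gibberellin with brassinosteroid genes, abscisic acid with cold response, and jasmonate genes. The light-harvesting list was tested on LHCB4.1, LHCB4.2 and LHCB4.3 of its 20 members, so its results do not extend to other light-harvesting genes. For 5 lists (salicylic acid, nitrate assimilation, carbon starvation, seed tissue and cell division) no member had a probe set of its own in the probe table. That table left 8730 tested probe sets without a gene, so such genes may still be on the array. A further 21 lists, 20 families of at least 10 genes sharing a symbol stem and the plastid-encoded genes, were added after the values had been opened and before any difference between genotypes was computed. Whether signals from the 3' IVT labelling follow the levels of plastid transcripts was not tested, so statements on plastid-encoded genes refer to array signal.

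Because the values are centred per probe set, the planned choice of the probe set with the highest mean was replaced by a fixed order of identifier types, and a planned filter on dim probe sets could not be run. Of 13356 genes, 146 had more than 1 probe set, and none of these is named.

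Genes were named by a fixed rule for each comparison. The rule took the mutated genes, then the 5 called genes with the largest rise and the 5 with the largest fall among probe sets with 1 gene and both arrays of each genotype apart. It then took up to 3 called members of each list that camera called or that had 3 or more called members, and 1 called member of any other list. Where camera called a list with no called member, 3 members were given as values. The rule counts a gene without a symbol by its locus name.

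Overlaps of calls were set beside the overlap of independent lists and beside unchanged values simulated with the same shared arrays and, added later, were repeated with the shared arrays split, 1 to each comparison. Called genes within 400 neighbouring genes of GBF1, HY5 and HYH were compared with the rest of the genome by two-sided Fisher's exact tests. Alternatives were quantile normalisation, centring of arrays, a trended robust prior, array weights, a fit of the compared genotypes alone, a replicate block, each array left out in turn, fold thresholds, an estimated correlation in camera, the mean of a gene's probe sets, a looser threshold for overlaps, and windows of 200 and 1000 genes. Added after seeing the data were the mean of 18 spike-in control probe sets as a covariate, the omission of the pair of arrays with high spike-in signal, crossed replicate numbers, a replicate block for the plastid gene median, and the tests of unevenness over chromosomes. Quantile normalisation was run on the centred values. It therefore gave all arrays the same spread of deviations from the probe set medians, and it can rescale differences between genotypes. With an array left out, the lone array of its genotype was assumed to vary like the other genotypes. The fit was tested on simulated data of the same size for gbf1 against wild type. It called 80 of 100 probe sets changed by a log2 of 1, 100 of 100 changed by a log2 of 2, and 10 of 22546 unchanged ones. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).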

Results

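Expression was measured in whole light-grown seedlings of 4 Arabidopsis genotypes, each on 2 arrays from separate biological replicates. GBF1, HY5 and HYH are bZIP transcription factors that act in the response of seedlings to light. The genotypes were wild type, gbf1, gbf1 hy5 and gbf1 hyh. Every value below is a log2 signal relative to the median of the probe set over the 8 arrays, or a log2 difference between genotype means with its standard error (SE, n = 2 arrays per genotype). In every called gene named by the fixed rule, both arrays of the one genotype lay above both arrays of the other.

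The arrays differed in quality measures that the genotypes do not define. The mean of the spike-in control probe sets was 1.79 on gbf1 replicate 2 and 1.499 on gbf1 hyh replicate 2, and between -0.522 and 0.268 on the other 6 arrays. The SD of the difference between replicate arrays was 0.366 in gbf1, 0.350 in gbf1 hyh, 0.239 in gbf1 hy5 and 0.236 in wild type. The main fit gives all genotypes the same spread for a probe set. Its p-values are therefore likely too small for gbf1 hyh against gbf1 and too large for gbf1 hy5 against wild type. Without both arrays of high spike-in signal, limma called 134, 1126, 337, 1236, 436 and 655 probe sets in the comparisons of gbf1, gbf1 hy5 and gbf1 hyh with wild type, of gbf1 hy5 and gbf1 hyh with gbf1, and of gbf1 hy5 with gbf1 hyh. The first principal component held 30.4% of the variance and set both gbf1 hy5 arrays (31.6 and 31.3) apart from the other 6.

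HYH (AT3G17609), the mutated gene with a probe set of its own, was lowest in gbf1 hyh. Its mean signal was -1.91 ± 0.173 (SD, n = 2) in gbf1 hyh and -0.933 ± 0.110 in gbf1 hy5, against 0.965 ± 0.156 in wild type and 1.82 ± 0.175 in gbf1. In the limma test HYH fell by 2.87 (SE 0.166, adjusted p = 5.1e-05) in gbf1 hyh and by 1.90 (adjusted p = 0.000698) in gbf1 hy5 against wild type. Its difference between gbf1 and wild type, 0.85, did not pass (adjusted p = 0.0854). Which part of the gene the probe set covers and which allele each mutant carries are not given in the sources used here.

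The comparison of gbf1 with wild type asks what loss of GBF1 changes. Few transcripts changed: 95 of 22746 probe sets (0.418%) passed the limma test, 51 higher and 44 lower in gbf1, and 85 of them differed by at least 2-fold. The root-hair expansin gene EXPA18 and the peroxidase genes AT1G30870 and AT3G49960 rose. QQS (AT3G30720), a gene linked to starch content, the cold-response gene COR15B and BCAT4, an enzyme of glucosinolate synthesis, fell. At an unadjusted p under 0.05 there were 1988 probe sets. Among the largest rises were AT3G02480 (2.87, SE 0.437, adjusted p = 0.0312), AT2G16005 (2.58, SE 0.268, adjusted p = 0.00528) and AT1G14960 (2.33, SE 0.289, adjusted p = 0.0138). The peroxidase genes rose by 2.28 (SE 0.197, adjusted p = 0.0027) for AT1G30870 and by 2.25 (SE 0.243, adjusted p = 0.00615) for AT3G49960. QQS fell by 3.601 (SE 0.286, adjusted p = 0.00173), AT4G30650 by 2.42, AT5G04380 by 2.34, COR15B by 2.16 (SE 0.334, adjusted p = 0.0331) and AT4G16146 by 1.92. BCAT4 fell by 1.56 (adjusted p = 0.022), the IQ-domain gene IQD22 by 1.05 (adjusted p = 0.0353) and the plastid gene ndhJ by 1.06 (adjusted p = 0.0481). Of the root hair markers measured, EXPA18 rose by 1.99 (SE 0.161, adjusted p = 0.00173), and EXPA7 differed by 1.18 (SE 0.235) without passing (adjusted p = 0.0933).

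By list, none of the 9 fixed lists tested was called by camera in gbf1. Of the 3 abscisic acid and cold genes measured, 1 fell, COR15B, and 1 fell when adjusted over the list alone (camera adjusted p = 0.0924). Of the 3 light-harvesting genes none passed over all genes and 1, LHCB4.3 (0.81), was higher when adjusted over the list alone (camera adjusted p = 0.0924, and 0.0389 upward without wild type replicate 2). Of the 8 chlorophyll genes none passed over all genes and 1, PORB (-0.82), was lower when adjusted over the list alone. Among the added families, the 10 EXPA genes (1 rose, 9 did not pass) and the 19 genes with GH symbols, a stem shared by GH3 and GH9 genes (1 rose, the cellulase-family gene GH9C1 by 1.55, 18 did not pass), were called upward by camera, both at adjusted p = 0.0186. Neither call held, at adjusted p = 0.828 with an estimated correlation. Both calls also ended without wild type replicate 1 (adjusted p = 0.303 for EXPA and 0.0614 for GH) and without gbf1 replicate 2 (0.0718 for both). Left-out arrays moved the count of 95 calls to 9 without wild type replicate 1, 10 without wild type replicate 2, 43 without gbf1 replicate 2 and 41 without either gbf1 hy5 array, and without gbf1 replicate 1 more were lower (70) than higher (68). It was 149 after quantile normalisation, 61 with a trended robust prior, 36 in the fit of the compared genotypes alone and 181 with the spike-in covariate. Of the 15 called genes named by the rule, 3 (QQS, AT5G04380 and EXPA18) passed with any 1 array left out, and for the others the adjusted p reached up to 0.426.

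**Figure D1:**
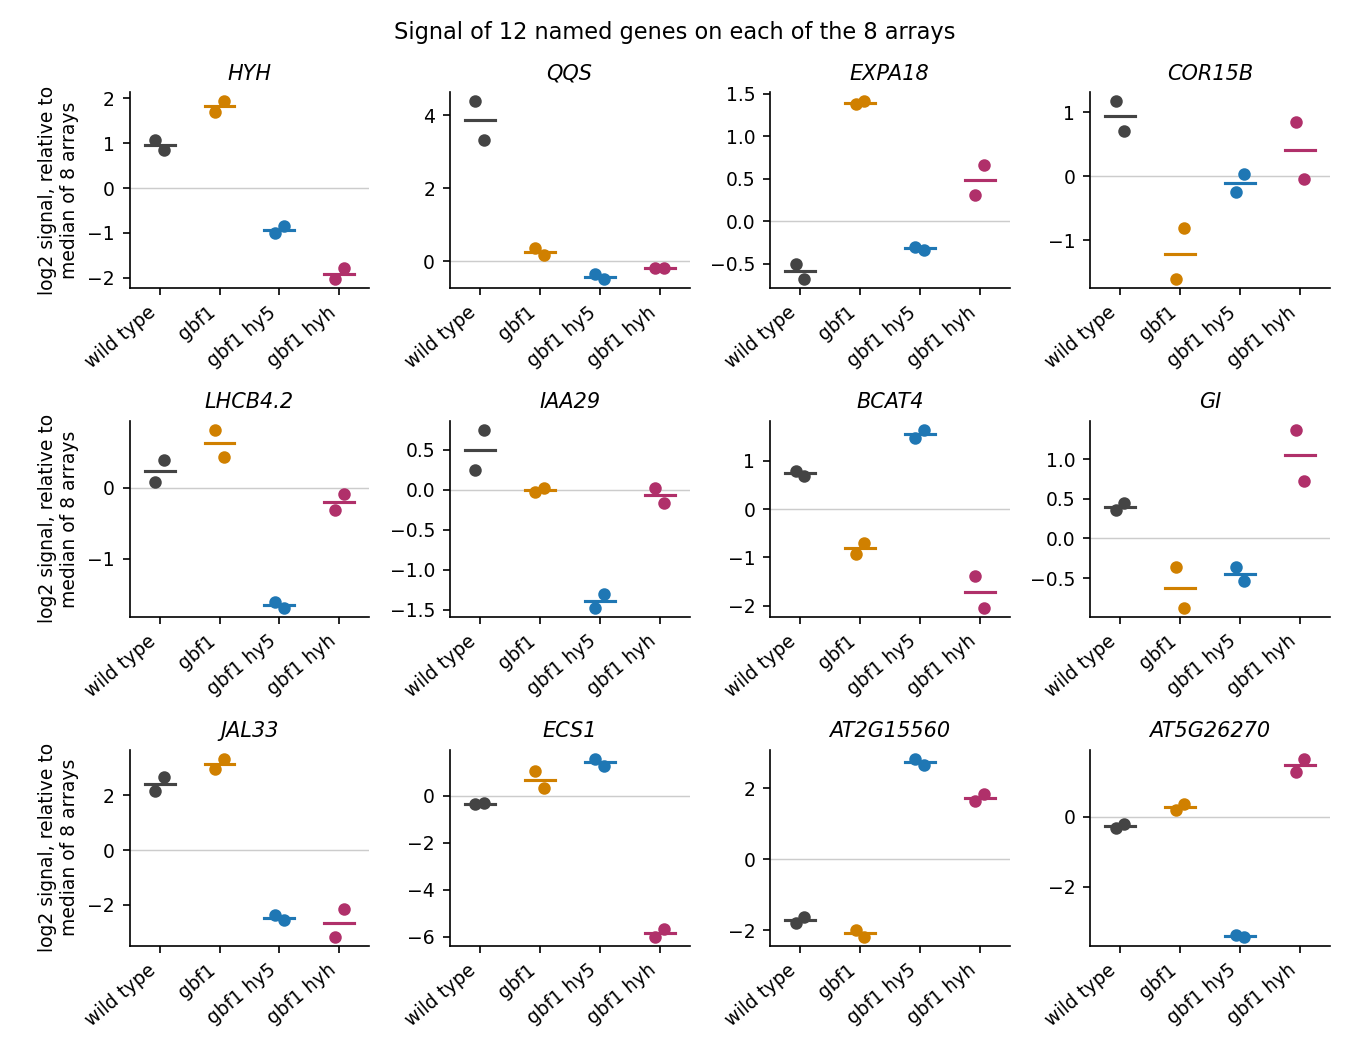
Signal of 12 genes on each array (vertical axis, log2 relative to the median of the 8 arrays) by genotype (horizontal axis), with a point for each array and a line at each genotype mean. HYH is lowest in gbf1 hyh at -1.91, and QQS is at 3.87 in wild type and between -0.417 and 0.265 in the mutants.

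The comparison of gbf1 hy5 with wild type covers the loss of GBF1 together with HY5, a promoter of light-dependent development. In limma 495 probe sets (2.18%) changed, 242 higher and 253 lower, and 319 differed by at least 2-fold. The light-harvesting gene LHCB4.2, the auxin-response gene IAA29 and the lectin gene JAL33 fell, and the carboxypeptidase-like gene scpl35 and the GH9B8 gene rose. By the naming rule, limited to probe sets tied to 1 gene, the largest rises were in AT2G15560 (4.47, SE 0.157, adjusted p = 3.86e-06), AT3G28320 (4.32, SE 0.230, adjusted p = 4.23e-05), AT1G29090 (3.21, SE 0.215), AT1G50290 (2.75, SE 0.330) and AT3G05150 (2.68, SE 0.149). The largest falls by that rule were in JAL33 (-4.91, SE 0.318, adjusted p = 0.000128), QQS (-4.28, SE 0.286), AT3G47250 (-4.19, SE 0.311), the histone gene HTB11 (-3.53, SE 0.512, adjusted p = 0.00922) and AT5G26270 (-3.14, SE 0.166).

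In the light-harvesting list, 1 of 3 measured genes fell in gbf1 hy5, LHCB4.2 by 1.89 (SE 0.181, adjusted p = 0.00113), and 2 fell when adjusted over the list alone. Camera called that list downward (adjusted p = 0.0168, and adjusted p = 0.363 with an estimated correlation), a call that ended after quantile normalisation (adjusted p = 0.109). In the auxin-response list, 1 of 6 fell, IAA29 by 1.90 (SE 0.185, adjusted p = 0.00121), 2 fell when adjusted over the list alone, and GH3.3 differed by -0.94 without passing over all genes (adjusted p = 0.072). Camera called the auxin list downward (adjusted p = 0.0142, and adjusted p = 0.363 with an estimated correlation). In the fit of the compared genotypes alone, which for this comparison is the same as that without the arrays of high spike-in signal, both lists were at adjusted p = 0.062. Of the 3 gibberellin receptor genes none passed over all genes and 1, GID1B (0.50), was higher when adjusted over the list alone (camera adjusted p = 0.0637, and 0.0242 upward without wild type replicate 2). Of 8 chlorophyll genes none passed over all genes, and PORB (-0.64) was lower when adjusted over the list alone. For the 3 cold genes the same holds of COR15B (-1.05).

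Of 29 serine carboxypeptidase-like genes, 2 rose in gbf1 hy5, scpl35 by 1.70 and SCPL49 by 0.93, and 27 did not pass. That family was called upward (adjusted p = 0.00547, and adjusted p = 0.866 with an estimated correlation), which ended without wild type replicate 2 (adjusted p = 0.153). Further family members that rose were the GH9B8 gene (1.98), GSTU20 (1.53), the tetraspanin gene TET2 (1.33) and the sugar transporter gene SWEET11 (0.84). CYP71B26 fell by 2.22 and RALFL27 by 1.21. Of 69 plastid-encoded genes, 1 fell, ycf3 by 0.94 (adjusted p = 0.0343), and 68 did not pass. Their median difference was -0.54, and 67 had values below wild type (camera adjusted p = 3.85e-22, and adjusted p = 0.866 with an estimated correlation). Without an array of either genotype compared the count of 495 calls was 146 (wild type replicate 1), 88 (wild type replicate 2), 148 (gbf1 hy5 replicate 1) or 111 (gbf1 hy5 replicate 2). It was 788 after quantile normalisation, 295 with a trended robust prior, 1320 with array weights (715 higher and 605 lower), 1126 in the fit of the compared genotypes alone (593 and 533) and 978 with the spike-in covariate. More were higher than lower in the last 3 of these and without either gbf1 array (305 and 304). Of 22 called genes named by the rule, 14 passed with any 1 array left out, while AT1G50290, HTB11, GSTU20, RALFL27, SCPL49, SWEET11, TET2 and ycf3 did not, with an adjusted p up to 0.313.

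The comparison of gbf1 hyh with wild type covers the loss of GBF1 together with HYH, the closest relative of HY5. In limma 292 probe sets (1.28%) changed, 83 higher and 209 lower, and 221 differed by at least 2-fold. The cell wall protein gene ECS1 (AT1G31580), JAL33 and the glucosinolate gene BCAT4 fell, and EXPA18 rose. By the naming rule, limited to probe sets tied to 1 gene, the largest falls were in ECS1 (-5.51, SE 0.238, adjusted p = 1.56e-05), JAL33 (-5.09, SE 0.318, adjusted p = 7.74e-05), AT1G66100 (-4.38, SE 0.247), AT3G47250 (-4.27, SE 0.311) and AT1G23960 (-4.19, SE 0.220). The largest rises by that rule were in AT3G28320 (4.61, SE 0.230, adjusted p = 2.38e-05), AT2G15560 (3.46, SE 0.157), AT3G05150 (3.07, SE 0.149), AT1G50290 (2.35, SE 0.330, adjusted p = 0.0112) and AT2G16005 (1.95, SE 0.268, adjusted p = 0.0103). The largest change over all probe sets in this comparison was in probe set 263174_at, which names no gene in the probe table used here and was chosen after its values were seen. It was 7.34 higher (SE 0.481, adjusted p = 9.97e-05), at 6.38 and 6.02 on the gbf1 hyh arrays and at 0.857 and 2.70 on the gbf1 hy5 arrays.

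None of the 9 fixed lists tested was called in gbf1 hyh against wild type. In the light-harvesting list no gene passed over all genes, and LHCB4.3 (0.53) was higher when adjusted over the list alone. Of the 2 glucosinolate genes measured, BCAT4 fell by 2.46 (SE 0.216, adjusted p = 0.000738), and UGT74B1 did not pass. EXPA18 rose by 1.08 (adjusted p = 0.0146). Of 11 genes with PRA symbols none passed, with PRA1.E at 0.60, PRA1.A1 at 0.60 and PRA8 at 0.45. Camera called that family upward (adjusted p = 0.0349, and adjusted p = 0.683 with an estimated correlation), which ended without wild type replicate 2 (adjusted p = 0.127), gbf1 hyh replicate 1 (0.171) or gbf1 hyh replicate 2 (0.059). In other families CYP71B26 fell by 2.03, GSTU20 by 1.35, SWEET16 by 1.28 and UGT76B1 by 0.99, and BGLU15 rose by 0.94. Of 69 plastid-encoded genes, 2 photosystem genes fell, psbK by 1.86 (adjusted p = 0.0492) and psbI by 1.501 (adjusted p = 0.0367). The median of the 69 was -0.37, and 60 had values below wild type (camera adjusted p = 2.9e-12, and adjusted p = 0.685 with an estimated correlation). The count of 292 calls was 68 without wild type replicate 1, 69 without wild type replicate 2, 158 without either gbf1 hy5 array and 123 without gbf1 hyh replicate 2, and 465 after quantile normalisation, 178 in the fit of the compared genotypes alone and 529 with the spike-in covariate. Of 20 called genes named by the rule, 11 passed with any 1 array left out, while AT1G50290, AT2G16005, EXPA18, BGLU15, GSTU20, SWEET16, UGT76B1, psbK and psbI did not, with an adjusted p up to 0.371.

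The comparison of gbf1 hy5 with gbf1 asks what the added loss of HY5 changes in gbf1 seedlings. In limma 1012 probe sets (4.45%) changed, 546 higher and 466 lower, with 519 at 2-fold or more. The chlorophyll synthesis genes CHLI2, CHLM and HEME2, the light-harvesting gene LHCB4.2, the flavonoid gene CHIL and EXPA18 fell, and BCAT4 and the gibberellin receptor gene GID1A rose. The naming rule was limited to probe sets with a gene of their own, and some other probe sets changed by more. By that rule the largest rises were in AT2G15560 (4.84, SE 0.157, adjusted p = 3.46e-06), AT3G28320 (4.46, SE 0.230) and AT1G50290 (3.55, SE 0.330). AT3G05150 (2.72, SE 0.149) and AT3G16670 (2.71, SE 0.382, adjusted p = 0.00505) followed. The largest falls by that rule were in JAL33 (-5.64, SE 0.318, adjusted p = 3.84e-05), AT3G47250 (-4.42, SE 0.311) and AT5G26270 (-3.68, SE 0.166). AT2G19970 (-3.31, SE 0.156) and the cytochrome P450 gene AT3G44970 (-3.01, SE 0.177) followed. HYH fell by 2.75 (adjusted p = 4.95e-05). The comparison therefore covers a lower HYH signal along with the loss of HY5, and the 2 cannot be told apart here.

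Of 8 chlorophyll genes, 3 fell in gbf1 hy5 against gbf1, CHLI2 by 0.78, CHLM by 0.76 and HEME2 by 0.62, 5 did not pass, and 4 fell when adjusted over the list alone (camera adjusted p = 0.122). LHCB4.2 fell by 2.28 (SE 0.181, adjusted p = 0.000258), the other two light-harvesting genes did not pass, and 2 fell when adjusted over the list alone. Camera called the light-harvesting list, here the 3 measured LHCB4 genes, downward (adjusted p = 0.00037, and adjusted p = 0.129 with an estimated correlation). IAA29 fell by 1.39 (adjusted p = 0.00381), 5 auxin genes did not pass, and 2 fell when adjusted over the list alone. The auxin list was called downward (adjusted p = 0.00877, and adjusted p = 0.238 with an estimated correlation), which ended without gbf1 replicate 2 (adjusted p = 0.0955) and without both arrays of high spike-in signal (0.142). GID1A rose by 0.90 (SE 0.204, adjusted p = 0.0416), GID1B (0.46) and GID1C (0.46) did not pass over all genes, and 3 rose when adjusted over the list alone. This list was called upward (adjusted p = 0.00877, and adjusted p = 0.238 with an estimated correlation), which ended without gbf1 replicate 1 (adjusted p = 0.0702). None of the 3 cold genes passed, with COR15B at 1.11, COR47 at 0.47 and COR15A at 0.37, and 3 were higher when adjusted over the list alone. Their list was called upward (adjusted p = 0.0143, and adjusted p = 0.238 with an estimated correlation), which ended without gbf1 hy5 replicate 2 (adjusted p = 0.0622). Of 7 flavonoid genes, 1 fell, CHIL by 0.84 (adjusted p = 0.0137), and 1 fell when adjusted over the list alone.

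BCAT4 rose by 2.37 (SE 0.216, adjusted p = 0.000596) in gbf1 hy5 against gbf1, and both root hair markers measured fell, EXPA18 by 1.71 (SE 0.161, adjusted p = 0.000659) and EXPA7, named after its values were seen, by 1.19 (SE 0.235, adjusted p = 0.0246). The call of EXPA7 ended in 3 of the 8 fits with 1 array left out, at an adjusted p up to 0.163. In the families GSTU20 (2.58), GH9B8 (1.51), TET2 (1.37), SCPL49 (1.35), scpl35 (1.19), UGT80B1 (1.18), TBL38 (0.89), BGLU40 (0.84) and SCPL34 (0.66) rose. Those that fell were GH9C1 (-1.86), SWEET2 (-1.62), CYP718 (-1.41), RALFL27 (-1.30), iqd21 (-0.91), UBC37 (-0.66) and GH3.17 (-0.65). Of the 69 plastid-encoded genes 5 fell, among them rps16 by 1.70, rps3 by 0.93 and ycf3 by 0.92. Their median was -0.50, and 63 had values below gbf1 (camera adjusted p = 1.45e-11, and adjusted p = 0.697 with an estimated correlation). The count of 1012 calls was 640 without either wild type array, 611 without gbf1 replicate 2, 280 without gbf1 hy5 replicate 1 and 241 without gbf1 hy5 replicate 2, and 566 in the fit of the compared genotypes alone and 1568 with the spike-in covariate. More were lower than higher after quantile normalisation (402 higher and 463 lower), in the fit of the compared genotypes alone (273 and 293), without both arrays of high spike-in signal (583 and 653), without either wild type array (311 and 329), without gbf1 replicate 2 (252 and 359) and without gbf1 hy5 replicate 1 (116 and 164) or 2 (92 and 149). Of 39 called genes named by the rule, 18 passed with any 1 array left out. Those that did not were CHLI2, CHLM, HEME2, CHIL, IAA29, GID1A, BGLU40, CYP718, GH3.17, iqd21, RALFL27, scpl35, SCPL34, SWEET2, TBL38, TET2, UBC37, UGT80B1, rps16, rps3 and ycf3, with an adjusted p up to 0.312.

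The comparison of gbf1 hyh with gbf1 asks the same of HYH. In limma 571 probe sets (2.51%) changed, 230 higher and 341 lower, and 354 differed by at least 2-fold. The clock gene GI, the protochlorophyllide reductase gene PORB, GID1A and COR15B rose, and ECS1, JAL33 and EXPA18 fell. By the naming rule, limited to probe sets tied to 1 gene, the largest falls were in ECS1 (-6.53, SE 0.238, adjusted p = 4.35e-06), JAL33 (-5.82, SE 0.318), ZW9 (AT1G58270, -5.27, SE 0.167, adjusted p = 2.8e-06), AT3G47250 (-4.50, SE 0.311) and AT1G23960 (-4.38, SE 0.220). The largest rises by that rule were in AT3G28320 (4.75, SE 0.230, adjusted p = 1.33e-05), AT2G15560 (3.83, SE 0.157), AT1G50290 (3.15, SE 0.330), AT3G05150 (3.104, SE 0.149) and AT2G40960 (3.04, SE 0.213). Probe set 263174_at, tied to no gene, rose by more (7.34, SE 0.481, adjusted p = 8.66e-05). HYH fell by 3.72 (adjusted p = 1.21e-05).

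GI rose by 1.67 (SE 0.237, adjusted p = 0.00762) in gbf1 hyh against gbf1. Of 8 chlorophyll genes 1 rose, PORB by 0.97 (SE 0.169, adjusted p = 0.0199), and 1 rose and 1 fell when adjusted over the list alone. GID1A rose by 1.16 (adjusted p = 0.0213), and 1 of the 3 receptor genes rose when adjusted over the list alone (camera adjusted p = 0.0897, and upward at 0.0353 without gbf1 hyh replicate 2 and at 0.0142 without both arrays of high spike-in signal). Of the 3 cold genes 1 rose, COR15B by 1.62 (SE 0.334, adjusted p = 0.0404), and 3 rose when adjusted over the list alone. Camera called the cold list upward (adjusted p = 0.0207, and adjusted p = 0.317 with an estimated correlation), which ended without gbf1 replicate 2 (adjusted p = 0.068) and gbf1 hyh replicate 1 (adjusted p between 0.00721 and 0.23 over the left-out arrays). No light-harvesting or flavonoid gene passed over all genes, and 1 light-harvesting and 2 flavonoid genes were lower when adjusted over the list alone. EXPA18 fell by 0.91 (adjusted p = 0.0215). Of 26 genes with CYP symbols, 3 fell, CYP71B26 by 1.22, CYP718 by 0.94 and CYP71B37 by 0.62. Camera called that family downward (adjusted p = 0.0366, and adjusted p = 0.649 with an estimated correlation), which ended without gbf1 replicate 1 (adjusted p = 0.17), gbf1 replicate 2 (0.0605) or gbf1 hyh replicate 1 (0.167). UGT87A2 (1.94), IQD22 (1.21), BGLU44 (1.08) and SCPL49 (0.85) rose, and SWEET2 (-2.09) and RALFL24 (-1.03) fell. Of 69 plastid-encoded genes, 4 fell, among them psbK by 1.75, psbI by 1.43 and rpl20 by 1.26. Their median was -0.32, with 52 values below gbf1 (camera adjusted p = 6.25e-06, and adjusted p = 0.914 with an estimated correlation), a call that ended without gbf1 replicate 2 (adjusted p = 0.613). The count of 571 calls was 316 without either wild type array, 346 without gbf1 replicate 2, 333 without either gbf1 hy5 array and 282 without gbf1 hyh replicate 2, and 286 with array weights, 90 in the fit of the compared genotypes alone and 1191 with the spike-in covariate. Of 28 called genes named by the rule, 14 passed with any 1 array left out, while PORB, GID1A, COR15B, EXPA18, BGLU44, CYP71B26, CYP718, CYP71B37, RALFL24, SCPL49, UGT87A2, psbK, psbI and rpl20 did not, with an adjusted p up to 0.201.

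The comparison of gbf1 hy5 with gbf1 hyh tests whether the double mutants differ. In limma 631 probe sets (2.77%) differed, 400 higher and 231 lower in gbf1 hy5, and 381 by at least 2-fold. ECS1, ZW9 and the glucosinolate genes BCAT4 and UGT74B1 were higher in gbf1 hy5, and LHCB4.2, IAA29, PORB and GI were lower. By the naming rule, limited to probe sets tied to 1 gene, the largest differences upward were in ECS1 (7.27, SE 0.238, adjusted p = 2.27e-06), ZW9 (4.603, SE 0.167), AT1G23960 (4.49, SE 0.220), AT4G02540 (3.46, SE 0.174) and BCAT4 (3.28, SE 0.216). The largest downward by that rule were in AT5G26270 (-4.88, SE 0.166, adjusted p = 2.27e-06), AT2G40960 (-4.03, SE 0.213), AT5G05750 (-2.83, SE 0.164), AT1G50060 (-2.42, SE 0.278) and AT5G54370 (-2.37, SE 0.382, adjusted p = 0.0125). HYH was 0.97 higher in gbf1 hy5 (SE 0.166, adjusted p = 0.0166), a call that ended after quantile normalisation (0.53, adjusted p = 0.16) and without gbf1 hy5 replicate 1 (adjusted p = 0.0955), gbf1 hy5 replicate 2 (0.174) or gbf1 hyh replicate 1 (0.0598).

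Of 3 light-harvesting genes, 1 was lower in gbf1 hy5 than in gbf1 hyh, LHCB4.2 (-1.45, SE 0.181, adjusted p = 0.00347), and 1 when adjusted over the list alone. Camera called the list downward (adjusted p = 0.00773, and adjusted p = 0.253 with an estimated correlation), which ended without gbf1 hyh replicate 1 (adjusted p = 0.059). GI (-1.50), IAA29 (-1.32), EXPA18 (-0.80) and PORB (-0.79) were lower, and adjusted over the list alone 2 of 8 chlorophyll and 2 of 6 auxin genes were lower. In the families GSTU20 (2.88), GH9B8 (1.77), AGL87 (1.51), SWEET17 (1.44), UGT74B1 (1.28), TET2 (1.27), BGLU40 (1.25), scpl35 (1.22), SCPL45 (1.17), GH9C2 (1.01) and scpl25 (0.77) were higher, and GH9C1 (-1.05), BGLU15 (-1.01) and BGLU44 (-0.95) were lower. None of the 21 added lists was called. The count of 631 calls was 380 without either wild type array, 175 without gbf1 hy5 replicate 1, 162 without gbf1 hy5 replicate 2 and 299 without gbf1 hyh replicate 2, and 389 with a trended robust prior, 376 in the fit of the compared genotypes alone and 1071 with the spike-in covariate. Of 30 called genes named by the rule, 11 passed with any 1 array left out, among them ECS1, ZW9, AT1G23960, AT4G02540, BCAT4, AT5G26270, AT2G40960, AT5G05750 and AT1G50060, and for the others the adjusted p reached up to 0.328.

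The Calvin cycle, expansin and jasmonate lists had no gene past the test over all genes and no camera call in any of the 6 comparisons, and adjusted over the list alone 1 expansin-list gene rose in gbf1 hy5 against gbf1. The only measured members of the lists for photoreceptors (FHL), UV-B (UGT84A1) and heat shock (ATHSP22.0) did not pass in any comparison either. Median, mean and camera direction differed in sign in some fixed lists. These were the auxin list (median 0.03, mean -0.04, downward) and the expansin list (-0.15, 0.10, downward) in gbf1 against wild type. In gbf1 hy5 against wild type they were the Calvin cycle list (-0.05, 0.03, downward), the flavonoid list (0.004, 0.01, downward) and the cold list (0.30, -0.12, upward). Against gbf1 they were the flavonoid list (0.04, -0.11, downward) and the expansin list (-0.07, 0.06, upward) in gbf1 hy5, and the expansin list (0.21, -0.04, upward) in gbf1 hyh. Between the double mutants they were the Calvin cycle list (-0.02, 0.08, upward) and the cold list (0.01, -0.16, downward).

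Probe sets called in the same direction in several mutants were compared. Against wild type, 3 were higher and 8 lower in all 3 mutants, which share the wild type arrays. Independent lists would share 0.00198 and 0.0045, and simulated unchanged values with the same wild type arrays, read at the unadjusted p that the calls reach, shared at most 1 higher and 3 lower in 20 simulations, so that part of the count may come from the shared arrays. Few unchanged values reach those p, so the simulated overlap was small by construction. The simulation was added after the count had been seen, and the probe sets named here were chosen after their values were seen. The differences of QQS were -3.60, -4.28 and -4.04 in gbf1, gbf1 hy5 and gbf1 hyh, those of AT5G04380 were -2.34, -2.37 and -2.22, those of AT5G35940 were -1.24, -1.38 and -1.01, and those of the expansin-like gene EXLA3 were -0.97, -1.25 and -1.24. AT1G29090 was higher by 2.07, 3.21 and 1.89, and AT2G16005 by 2.58, 2.56 and 1.95. Probe set 246211_at, which names no gene in the probe table used here, differed by -4.37, -4.48 and -4.19. With 1 array left out the calls of EXLA3 and AT5G35940 ended in each mutant, at an adjusted p up to 0.411, those of AT2G16005 ended in gbf1 and gbf1 hyh, at up to 0.124, and that of AT1G29090 ended in gbf1, at up to 0.0856.

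Pairs of comparisons shared more calls in the same direction than independent lists would, and each pair also shares the 2 arrays of 1 genotype. The calls of gbf1 and gbf1 hy5 against wild type shared 6 higher and 9 lower probe sets, where independent lists would share 0.543 and 0.489, and a further 4 were higher in gbf1 and lower in gbf1 hy5 and 6 the reverse (0.567 and 0.468). Those of gbf1 and gbf1 hyh shared 13 and 18 (0.186 and 0.404 for independent lists), with 7 and 2 in opposite directions (0.469 and 0.161). Those of gbf1 hy5 and gbf1 hyh shared 27 and 74 (0.883 and 2.33), with 9 and 2 in opposite directions (2.22 and 0.923). Against gbf1, the double mutants shared 108 higher and 143 lower probe sets (5.52 and 6.99), with 8 and 5 in opposite directions (8.19 and 4.71). Simulated unchanged values with the same shared arrays, read at the unadjusted p that the calls of each comparison reach, shared at most 4, 4, 9 and 11 in the same direction and 0 in opposite directions in these pairs over 20 simulations, which were added after the overlaps had been seen. Few unchanged values reach those p, so these overlaps were small by construction. They do not measure what the shared arrays add among changed probe sets. The covariance of the differences was 0.0173, 0.0254, 0.0442 and 0.0796 in these pairs, against simulated values of 0.0187, 0.0187, 0.0187 and 0.0186. The simulation gave every genotype the same spread, while replicate arrays differed more in gbf1 (SD 0.366) than in wild type (0.236). Its value is therefore likely too low where the gbf1 arrays are shared and too high where the wild type arrays are. With the shared arrays split, 1 to each comparison, in either way, which was added after the overlaps had been seen, the covariance was -0.00022 and 0.00708 for gbf1 and gbf1 hy5, 0.0118 and 0.0112 for gbf1 and gbf1 hyh, 0.0343 and 0.0264 for the double mutants against wild type and 0.0534 and 0.0389 for them against gbf1. The calls shared in the same direction were then 4 and 4 for gbf1 and gbf1 hy5, 3 and 6 for gbf1 and gbf1 hyh, 19 and 21 for the double mutants against wild type and 147 and 123 against gbf1, and part of each excess with all arrays may come from the shared arrays. Neither the simulation nor the split covers variation shared by same-numbered arrays, which was largest for gbf1 and gbf1 hyh (r = 0.336). The labels give an ecotype only for wild type. A genetic background shared by the double mutants therefore cannot be told apart from effects of losing HY5 or HYH in the calls they share. The same limit holds for the calls in gbf1 and for those in only 1 of the double mutants. HYH was also lower in both double mutants than in gbf1, by 2.75 in gbf1 hy5 and 3.72 in gbf1 hyh. No hy5 or hyh mutant without gbf1 was measured, so a part of low HYH signal in the shared calls was not tested.

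Probe sets called in gbf1 against wild type were followed in the double mutants, where many differed from gbf1 in the other direction. Of the 51 higher in gbf1, 40 (78.4%) fell in gbf1 hy5 and 27 (52.9%) fell in gbf1 hyh against gbf1, EXPA18 in both and GH9C1 in gbf1 hy5 among them. Of the 44 lower in gbf1, 31 (70.5%) rose in gbf1 hy5, BCAT4 among them, and 25 (56.8%) rose in gbf1 hyh, COR15B and IQD22 among them. Independent lists would share 1.05, 0.765, 1.06 and 0.445, and simulated unchanged values, read at the p that the calls reach, shared at most 5 in opposite directions for gbf1 hy5 and 4 for gbf1 hyh. Few unchanged values reach that p, so this overlap was small by construction. With the gbf1 changes kept in the double mutants, also added later, at most 7.27 and 5.46% of those higher changed the other way in gbf1 hy5 and gbf1 hyh. Of those lower it was at most 8.7 and 7.5%, in 20 simulations. The covariance with the gbf1 difference was -0.0608 for gbf1 hy5 and -0.0527 for gbf1 hyh, against -0.0186 simulated for each. All these simulations gave every genotype the same spread, while replicate arrays differed more in gbf1 (SD 0.366) than in wild type (0.236). They therefore likely understate what the shared gbf1 arrays give. The median difference from wild type of the 51 went from 1.65 in gbf1 to 0.25 in gbf1 hy5 and 0.72 in gbf1 hyh, and that of the 44 from -1.29 to -0.22 and -0.31. Some passed wild type: 4 of the 51 were called lower than wild type in gbf1 hy5 and 7 in gbf1 hyh. Of the 44, 6 and 2 were called higher than wild type. BCAT4 was at 1.48 and 1.65 on the gbf1 hy5 arrays and at 0.798 and 0.693 in wild type. Both sets were chosen for their gbf1 values, and part of the return may come from the shared gbf1 arrays. With 1 gbf1 array for the choice and the other for the comparison with the double mutants, which was added after the overlap had been seen, the covariance was -0.0286 and -0.026 for gbf1 hy5 and -0.0278 and -0.0107 for gbf1 hyh. Chosen on gbf1 replicate 1, 22 of 31 higher and 8 of 12 lower probe sets were called the other way in gbf1 hy5, and 14 and 6 in gbf1 hyh. Chosen on gbf1 replicate 2, 30 of 68 and 19 of 70 were called the other way in gbf1 hy5, and 10 and 13 in gbf1 hyh. After quantile normalisation the shares in gbf1 hy5 and gbf1 hyh were 50.7 and 22.1% of those higher and 45.8 and 37.5% of those lower in gbf1. In gbf1 hyh the shares of those higher and lower in gbf1 were 4.35 and 23.1% in fits of the compared genotypes alone and 29.0 and 34.8% with a trended robust prior, and array weights gave 29.4% of those higher. Over the left-out arrays the share of those higher ranged from 63.0 to 85.7% in gbf1 hy5, the latter over 7 probe sets, and from 23.0 to 66.2% in gbf1 hyh. That of those lower was 42.9% in gbf1 hy5 without gbf1 hy5 replicate 1 and 35.7% without gbf1 hy5 replicate 2. Without either wild type array 3 probe sets were lower in gbf1, and 0 of the 3 rose in either double mutant.

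**Figure D2:**
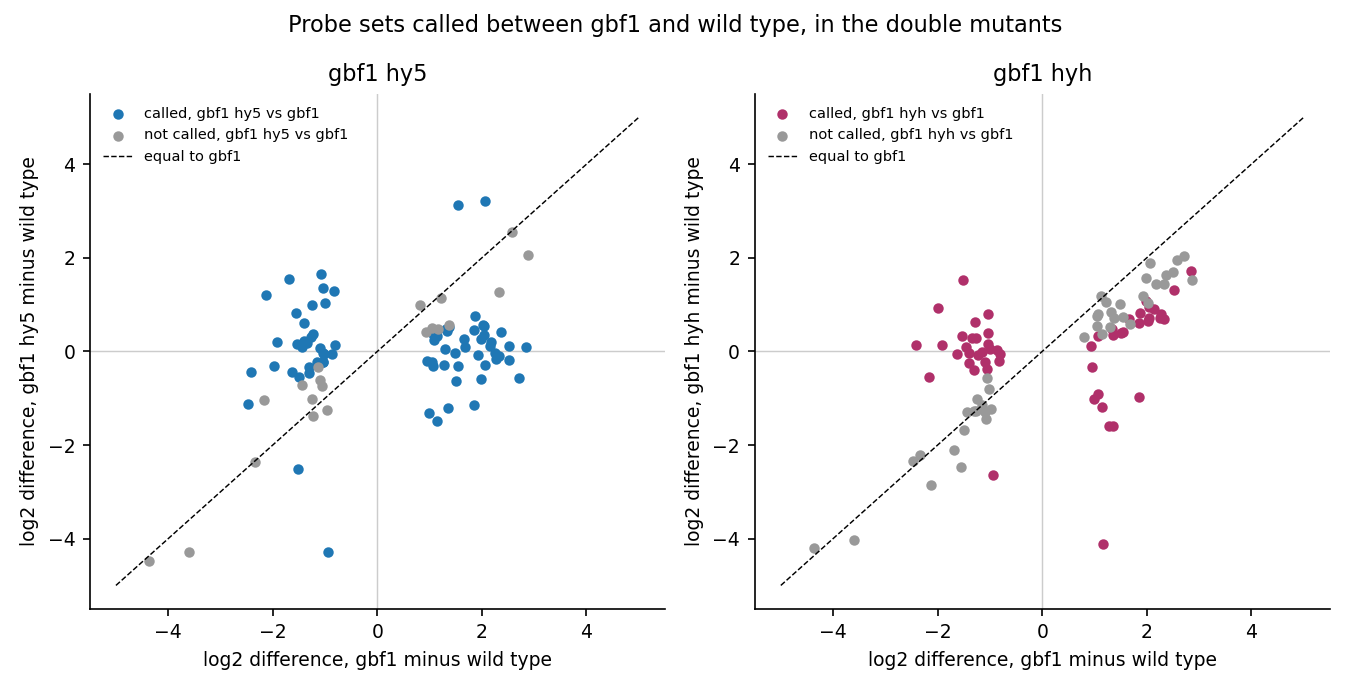
Log2 difference of each probe set called in gbf1, gbf1 minus wild type (horizontal axis) against double mutant minus wild type (vertical axis), with coloured points for those called against gbf1, grey points for the rest and a dashed line where the double mutant equals gbf1. Of the 51 probe sets higher in gbf1, 40 were called lower in gbf1 hy5 than in gbf1.

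Genes near the mutated loci were compared with the rest of the genome. None of 18 two-sided Fisher's exact tests passed within 400 neighbouring genes of GBF1, HY5 or HYH, the smallest adjusted p being 0.609 in gbf1 hyh near HYH, where 8 of 318 genes were called against 147 of 12898 elsewhere. By whole chromosome, in 30 tests chosen after the calls had been seen, 13 of 2982 genes (0.436%) on chromosome 5 were called in gbf1 hyh against wild type and 1.397% elsewhere (adjusted p = 4.29e-05, Fisher's exact test). In the same comparison 1.88% were called on chromosome 3 and 1.00% elsewhere (adjusted p = 0.00215), and 1.61% on chromosome 1 and 1.03% elsewhere (adjusted p = 0.0317). On chromosome 3, 2.72% were called in gbf1 hy5 against wild type and 1.48% elsewhere (adjusted p = 0.000191, Fisher's exact test). With calls thinned to 1 per 10 neighbouring genes, the unevenness over 98 bins did not pass in gbf1 hy5 against wild type (permutation p = 0.059, adjusted p = 0.0708, and adjusted p = 0.012 before thinning) and passed in gbf1 hyh against wild type (adjusted p = 0.003). In the same permutation test it passed in gbf1 hy5 against gbf1 (adjusted p = 0.004), gbf1 hyh against gbf1 (0.0135) and between the double mutants (0.003). It did not pass in gbf1 against wild type (adjusted p = 0.38). Against gbf1 the shares were also higher on chromosome 3, in gbf1 hy5 (adjusted p = 0.00481) and gbf1 hyh (0.0282), and lower on chromosome 5 in gbf1 hyh (0.000191). Between the double mutants the share was higher on chromosome 1 (adjusted p = 4.29e-05) and lower on chromosomes 3 (4.29e-05) and 5 (0.0317).

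**Figure D3:**
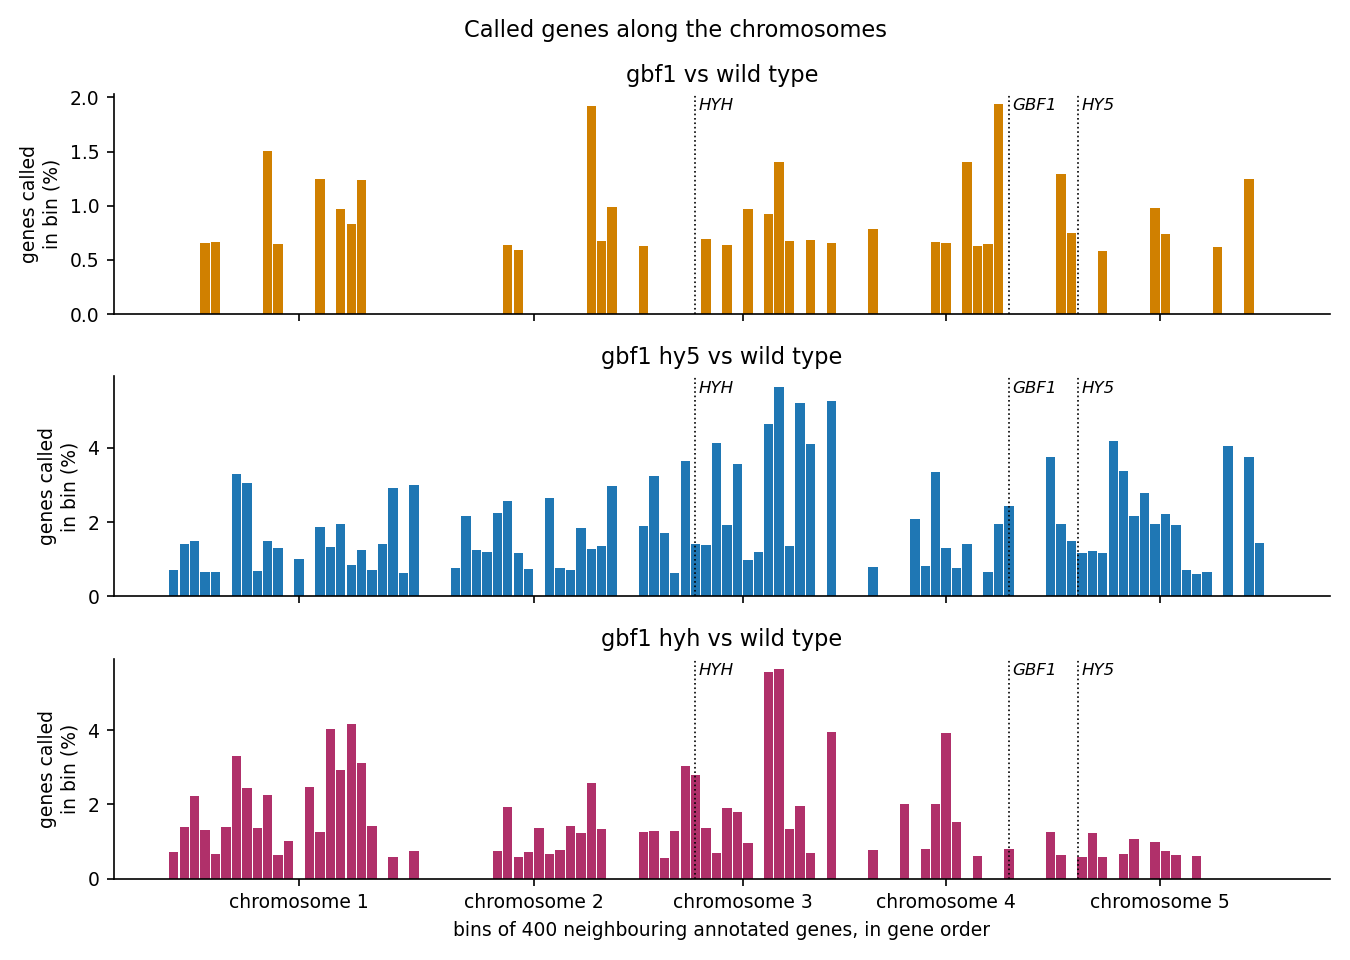
Percent of genes called (vertical axis) in bins of 400 neighbouring annotated genes along the 5 chromosomes (horizontal axis) for the 3 mutants against wild type, with dotted lines at HYH, GBF1 and HY5. In gbf1 hyh the calls are fewest on chromosome 5, at 0.436% of its genes.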

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

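The average over spike-in controls and the search for opposite changes were chosen after the values were seen, while the test between the double mutants was planned.

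Control RNA signals, which no comparison uses, stood apart on a pair of arrays: the mean of the spike-in control probe sets was 1.79 on gbf1 replicate 2 and 1.499 on gbf1 hyh replicate 2, against -0.522 to 0.268 on the other 6 arrays.

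The change on adding hy5 to gbf1 differed from that on adding hyh in 631 probe sets by the limma test of the difference itself, which rests on the same gbf1 hy5 against gbf1 hyh contrast as in the results. Of these, 8 rose in gbf1 hy5 and fell in gbf1 hyh against gbf1, and 5 did the opposite, where independent lists would share 8.19 and 4.71. Simulated unchanged values with the same gbf1 arrays shared 0 in opposite directions in 20 simulations. Unchanged values yield few calls, so that outcome was close to fixed in advance. The genes among the 8 and 5 probe sets, chosen after their values were seen, were AT2G43535 (1.56 in gbf1 hy5 and -1.71 in gbf1 hyh), AT1G12400 (0.82 and -2.09), AT1G58150 (0.97 and -1.47), AT5G26270 (-3.68 and 1.198), AT2G40960 (-0.99 and 3.04) and AT1G52060 (-1.09 and 0.86). With 1 array left out, both calls of AT5G26270 held in all 8 fits. The call in gbf1 hy5 ended in 5 of the 8 for AT2G40960, 4 for AT1G12400, 3 for AT1G58150, 2 for AT1G52060 and 1 for AT2G43535, and that in gbf1 hyh ended in 6 for AT1G52060, at an adjusted p up to 0.242.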

How the results depend on the processing

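The spike-in covariate, the omission of both arrays of high spike-in signal, the crossed replicate numbers and the alternatives for the probe sets called in gbf1 were chosen after the data had been seen. Counts below follow the order gbf1, gbf1 hy5 and gbf1 hyh against wild type, gbf1 hy5 and gbf1 hyh against gbf1, and gbf1 hy5 against gbf1 hyh, with values of 95, 495, 292, 1012, 571 and 631, and only counts that moved by more than 1.5 times are given for a setting. Quantile normalisation gave 149, 788 and 465 in the first 3. Run on centred values, it gave all arrays the same spread, although their SDs ranged from 0.199 (wild type replicate 1) to 0.341 (gbf1 hyh replicate 2). Moves under this setting may therefore come from that rescaling. A trended robust prior gave 61 in the first, 295 in the second and 389 in the last. Array weights gave 1320 for gbf1 hy5 against wild type and 286 for gbf1 hyh against gbf1. Fits of the compared genotypes alone gave 36, 1126, 178, 566, 90 and 376. The spike-in covariate gave 181, 978, 529, 1568, 1191 and 1071. Leaving out both arrays of high spike-in signal gave 1126 for gbf1 hy5 against wild type, the same fit as that of those genotypes alone. Adding a 2-fold minimum gave 319, 519, 354 and 381 for gbf1 hy5 against wild type and the last 3. At 2-fold with no test there were 175 for gbf1 against wild type and 593 for gbf1 hy5 against gbf1. With 1 array left out the counts ranged over 9 to 138, 88 to 609, 68 to 365, 241 to 1276, 282 to 660 and 162 to 794. A replicate block gave 120, 544, 338, 1224, 654 and 736, within 1.5 times, although same-numbered arrays correlated at only -0.114 to 0.336 across genes. The highest value was that of gbf1 with gbf1 hyh, whose replicate 2 arrays are those of high spike-in signal. With the numbers of gbf1 hy5 crossed, the block gave 877 for the last comparison. For HYH between the double mutants, quantile normalisation gave 0.53 (adjusted p = 0.16), and 1 array left out gave 0.851 to 1.096. With an estimated correlation the adjusted p of the called fixed lists was 0.363 for light harvesting and auxin in gbf1 hy5 against wild type. Against gbf1 it was 0.129 for light harvesting, 0.238 for auxin, gibberellin and cold in gbf1 hy5 and 0.317 for cold in gbf1 hyh, and it was 0.253 for light harvesting between the double mutants. That setting also tests on the 4 residual degrees of freedom, and the estimate for light harvesting (-0.14) lay below the preset. Light harvesting in gbf1 hy5 against wild type had an adjusted p of 0.109 after quantile normalisation. It and auxin were both at 0.062 in the fit of those genotypes alone, which is there the same as that without the arrays of high spike-in signal. Leaving out those arrays gave 0.142 for auxin in gbf1 hy5 against gbf1. Over left-out arrays the adjusted p ranged from 0.00762 to 0.0955 for auxin, 0.00381 to 0.0702 for gibberellin and 0.0134 to 0.0622 for cold in gbf1 hy5 against gbf1. It ranged from 0.00721 to 0.23 for cold in gbf1 hyh against gbf1 and from 0.00813 to 0.059 for light harvesting between the double mutants. At an unadjusted p under 0.01, the pairs of mutants against wild type (gbf1 with gbf1 hy5, gbf1 with gbf1 hyh, and the double mutants) and the double mutants against gbf1 shared 123, 165, 301 and 621 probe sets in the same direction and 68, 47, 49 and 37 in opposite directions. The gbf1 comparison shared 365 and 342 in opposite directions, and 19 and 11 in the same, with gbf1 hy5 and gbf1 hyh against gbf1. The plastid-encoded list in gbf1 against wild type, not called with all arrays, was called upward without gbf1 replicate 1 (adjusted p = 0.0492) and downward without gbf1 replicate 2 (9.34e-09), without wild type replicate 1 (1.87e-05) and after quantile normalisation (0.0084), a range of 9.34e-09 to 0.433. Other added lists gained calls in gbf1 against wild type, SWEET without wild type replicate 2 (adjusted p = 0.0362) and SWEET and VPS without gbf1 replicate 1 (0.0492 for both). The EXPA list gained a call in gbf1 hyh against gbf1 in fits of those genotypes alone (0.0415), with a replicate block (0.0329) and without gbf1 hyh replicate 2 (0.0378), and the plastid-encoded list between the double mutants with a replicate block (0.041) and without gbf1 hy5 replicate 2 (9.47e-05). Among probe sets called in gbf1, quantile normalisation lowered the shares that changed the other way to 50.7 and 22.1% of those higher and 45.8 and 37.5% of those lower, in gbf1 hy5 and gbf1 hyh. The cause of these moves was not tested, except that a 2-fold minimum can only remove calls. The main fit assumes the same spread in all genotypes, while replicate arrays differed more in gbf1 and gbf1 hyh than in wild type and gbf1 hy5. Its counts and adjusted p carry that limit. Of 3120 alternatives for 195 named values, 2571 kept direction and call status, 545 kept direction and lost the call, 4 kept direction and gained it, and 0 reversed. Values called in neither fit count among those kept. Called genes named by the rule had the arrays of the compared genotypes apart, so leaving out an array could not reverse them. Leaving out an array of another genotype does not change the difference at all. The count of reversals is therefore no measure of robustness. The planned filter on dim probe sets was not run, because values centred per probe set hold no level, and signal over background cannot be judged for the same reason.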

Other observations

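The tests in this part were chosen after the result was seen, apart from the test for segments of another accession and camera with an estimated correlation, which were planned.

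Genes called in gbf1 hyh against wild type lay unevenly over the chromosomes, with 0.436% of genes called on chromosome 5 and 1.397% elsewhere, and 1.88% on chromosome 3 and 1.00% elsewhere. Neighbouring duplicated genes called together are argued against as the whole cause, since with calls thinned to 1 per 10 neighbouring genes the permutation p over 98 bins was 0.001, the smallest that 1000 permutations can give. Segments of another accession might place rises and falls in the same bins, but the correlation over bins of the shares that rose (49 genes) and fell (107 genes) was 0.107 (permutation p = 0.144), too weak to decide. Because the labels give an ecotype only for wild type, such segments and a regional effect of the genotype, which was not tested, cannot be told apart.

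Many probe sets called in gbf1 differed from gbf1 in the other direction in gbf1 hy5 and gbf1 hyh, some of them past wild type. The shares were 78.4 and 52.9% of those higher and 70.5 and 56.8% of those lower. Quantile normalisation, which gives all arrays the same spread, lowered them to 50.7 and 22.1% and to 45.8 and 37.5%. In fits of the compared genotypes alone the share of those higher was 4.35% for gbf1 hyh. For those lower the pattern was not kept without either wild type array. Noise of gbf1 replicate 2 is argued against for the higher set, since 100 probe sets chosen on that array differed by a median of at least 0.943 between the arrays held out, while for the lower set it stays open, since of the medians of 0.358 (bootstrap SE 0.0871) and 0.521 (bootstrap SE 0.0764) the smaller passed the bound of 0.3 by less than its SE. A choice of extreme values is argued against for the higher set, where the double mutants lay below the held-out gbf1 array by a median no closer to 0 than -0.473, but it stays open for the lower set, where the median, signed in the chosen direction, was between -0.894 and -0.218 in gbf1 hy5 and between -0.454 and -0.00137 in gbf1 hyh over the choices of arrays, and passed the bound of -0.3 only in some. A larger share of root tissue in gbf1 seedlings might raise EXPA18, and the other root marker measured, EXPA7, differed by 1.18 without passing, so with 2 markers this cannot be told apart from a change in root hair genes. The bootstrap drew from the 100 probe sets on fixed arrays, so its SE does not measure variation between arrays or RNA samples. The split by direction and the use of the bootstrap SE were added after the values were seen. An effect of losing HY5 or HYH that offsets the loss of GBF1 remains as an untested biological explanation.

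Plastid-encoded genes had lower medians in both double mutants than in wild type, at -0.373 and -0.103 on the gbf1 hy5 arrays and -0.115 and -0.0497 on the gbf1 hyh arrays, against 0.0651 and 0.433 in wild type. The gbf1 arrays were at -0.0673 and 0.372, so gbf1 replicate 1 lay between the gbf1 hyh arrays. Whether signals from the 3' IVT labelling follow plastid transcript levels was not tested. RNA integrity, read from the 5' and 3' control probe sets, stays open. The difference of gbf1 hy5 from wild type was -0.54 (SE 0.0878) with that measure as a covariate and -0.49 (SE 0.225) without it, and in gbf1 hyh it was -0.53 (SE 0.0964) and -0.33 (SE 0.225). The fit with the covariate has 3 residual degrees of freedom, and its 95% intervals were -0.824 to -0.265 and -0.84 to -0.226. Replicate 2 was higher than replicate 1 in both measures in every genotype, so the covariate also stands for the replicate number. It therefore cannot decide for or against RNA integrity. Arrays that differ in all plastid genes at once stay open, since the camera calls were lost with an estimated correlation of 0.452 among these genes, and since without a covariate the 95% intervals of the differences from wild type, -1.11 to 0.138 in gbf1 hy5 and -0.957 to 0.294 in gbf1 hyh, held 0. The replicate gap of up to 0.44 had the same sign in every genotype, and with the replicate number as a block, chosen after this was seen, the intervals were -0.853 to -0.121 and -0.697 to 0.0346, so that with 2 arrays per genotype such array differences and an effect of genotype, which was not tested apart from them, cannot be told apart.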
